A study of Mus musculus with 20 samples.

How the data were processed

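The study measured RNA from the medial prefrontal cortex of C57BL/6 mice that had received an injection of PBS or of CDS into that region, per the labels. CDS is not spelled out in the labels, and the series title speaks of a model in which microglia, the resident macrophages of the brain, are depleted. The 20 samples form 4 groups of 5: PBS and CDS at 5 days after injection (5 dpi, postnatal day 47), and PBS and CDS at 12 weeks of age (postnatal day 84, 6 weeks after injection). The labels number the samples within each group. They do not say how the samples relate across groups, so p-values measure the spread between these samples. Total RNA was extracted from frozen tissue, and stranded libraries were made from 400 ng of RNA after removal of ribosomal RNA, per the labels' protocols. Such libraries hold unspliced as well as spliced transcripts.

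Per the submitters' processing notes, the tools were STAR, featureCounts and DESeq2 and the genome build was GRCm38.p5; versions are not given in the sources used here. The authors deposited 2 comparison tables, 1 for each time. Each holds a log2 fold change of CDS over PBS and a q-value per gene, per the file headers. Both tables list the same 20375 genes. They hold no per-sample values, no mean levels and no unadjusted p, so the depth per sample is unknown, and no interval that needs counts is given. The number of columns of per-sample values left unused was 0. Strand handling in counting and filters on low genes are not given in the sources used here. Genes of near-identical families, such as the histone, globin, Cd209 and Oas genes, share reads, and their separate values are uncertain.

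The symbol was blank for 4083 genes, of which 4015 took a name from the reference through their gene ID; 20300 IDs matched in all. Coordinates, transcript classes and genomic spans came from GENCODE M21 on GRCm38, which held 20306 of the IDs and lacked 69. Its primary chromosomes have the same sequence as the build of the authors.

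Genes were called past the threshold where the authors' deposited q-value was under 0.05, with no new test. The q-values were assumed to be a Benjamini-Hochberg adjustment over all genes, and p was recovered as q times rank over 20375. A signed z followed from p, and a standard error, called implied here, from the log2 fold change over z. The bounds that ties left on p at 5 dpi lay at most 1.04-fold apart. At 12 weeks 20103 genes shared the highest q of 0.999997, so that p and the implied standard error were recovered for 272 genes. A tied gene had a p of at least 0.0134. For the 272 genes the implied standard error at 12 weeks was 0.992 of that at 5 dpi (median; quartiles 0.973 and 1.01). These genes were selected for small p at 12 weeks.

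A total of 33 lists with 479 entries, of which 452 were measured, were tested with cameraPR of limma 3.58.1 (R 4.3.3) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. No estimated correlation could be had, because the tables hold no per-sample values. At 5 dpi the statistic was the signed z. At 12 weeks the planned signed z could not be recovered for most genes, and the ranks of the log2 fold change were used in its place, a departure from the plan. A two-sided Fisher exact test compared called members with all other genes. Counts adjusted over the list alone used the recovered p; at 12 weeks the tied genes were given their upper bound, so that these counts are minimums. Each list's median was set against 10000 random lists matched on 10 bins of the implied standard error at 5 dpi, which stand in for a match on expression level. The random lists were drawn from all transcript classes. The difference between times was a z of the log2 fold changes at 12 weeks minus those at 5 dpi over the root of the summed squared implied standard errors. It was tested two-sided over the 272 genes with both, and over all genes, where those lacking a 12-week standard error took that of 5 dpi, or the smallest the tied q allows where that was larger. Lists were compared between times with cameraPR on the z over all genes, at preset correlations of 0.01 and 0.05, a test chosen after the data were seen. Overlap was tested per direction with Fisher's exact test.

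The lists, the tests other than those named above as changed or chosen later, and most alternatives were fixed before the data were examined. The genes named were the 7 markers Tmem119, P2ry12, Cx3cr1, Csf1r, Aif1, Itgam and Gfap; the 10 largest rises and 10 largest falls among genes past the threshold, without predicted genes and those lacking a symbol; up to 4 members of each list with the smallest p; and the 5 largest differences between times in each direction. Some genes that this rule takes are not reported here. Other genes named were chosen after their values were seen. Alternatives were q under 0.01 and 0.1, a fold of at least 1.5, Bonferroni adjustment, a preset correlation of 0.05, other list statistics, lists without shared members, and other sets of genes. Chosen after seeing the data were a recount over protein-coding genes, the removal of a trend with genomic span (40 bins of protein-coding genes) and transcript class, and the 12-week tests that borrow the 5 dpi standard error. Leaving out samples, other splits of the samples and a search for outlying samples could not be done without per-sample values.

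The recovery of p and the tests of single genes were checked on simulated tables of 20375 genes built with the implied standard errors at 5 dpi. The true p lay within the recovered bounds for 100% of genes. That follows by construction where q is a Benjamini-Hochberg adjustment over all genes, as in the simulated tables. It cannot show whether the authors' q-values were made that way, which remains an assumption. At q under 0.05, 71.0% of genes changed by 1 and 91.0% of those changed by 2 on the log2 scale were recovered, and 4.14% of calls were unchanged genes. The difference test, over all genes and with known errors, recovered 84.0% of genes changed by 2 at 1 time, with 5.62% unchanged among its calls. It was not simulated for the selected 272 genes. For lists, independent normal values were drawn in place of the signed z, and 3.64% of 660 unchanged lists had a p under 0.05. With no correlation between genes, that rate does not cover lists of co-expressed genes, and ranks were not simulated. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.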

Results

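RNA from the medial prefrontal cortex was compared between mice injected with CDS and mice injected with PBS, at 5 days after injection and at 12 weeks of age. Each of the 4 groups held 5 samples. The data are the authors' own comparisons, a log2 fold change of CDS over PBS and a q-value for 20375 genes at each time. Errors given below are standard errors implied by those values. Depth per sample is unknown.

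The comparison at 5 dpi asked what differed soon after the injection. Markers of resting microglia, markers of oligodendrocyte precursors (the dividing cells that give rise to myelinating oligodendrocytes) and interferon-induced genes were lower in CDS than in PBS cortex. Cell cycle genes, cholesterol synthesis genes and markers of reactive astrocytes were higher. In the authors' deposited table, 1207 genes had a q under 0.05, of which 560 were higher and 647 lower in CDS. A difference of at least 2-fold was found for 367 of them, 104 higher and 263 lower.

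All 21 homeostatic microglia genes fell, with a median log2 fold change of -1.32 in the authors' deposited table (cameraPR adjusted p = 3.85e-99, and 21 also when adjusted over the list alone). At a preset correlation of 0.05 the cameraPR adjusted p was 4.96e-60. The size of such a p depends on the correlation between members, which could not be estimated. The purinergic receptor P2ry12 (chromosome 3, 59216272 to 59262871, minus strand) fell by 2.70 on the log2 scale, 6.48-fold, with an implied SE of 0.19 (q = 1.23e-43, the authors' deposited table). The fructose transporter Slc2a5 (chromosome 4, 150119283 to 150144169, plus strand) fell by 2.82 with an implied SE of 0.17 in the authors' deposited table (q = 1.39e-56). P2ry13 and Selplg fell as well, at -2.45 and -2.18 (the authors' deposited table, q = 1.09e-50 and 9.89e-41). The fixed markers Itgam, Cx3cr1, Csf1r and Tmem119 fell, at -1.92, -1.59, -1.49 and -1.25, as did Aif1, which encodes IBA1, at -0.50 in the authors' deposited table (q = 0.0467 for Aif1). Other lists shared several of these falls. Of 15 complement genes, 5 fell and 1 rose; the authors' deposited table gave -1.92 for Itgam and -1.05, -0.96 and -1.07 for C1qa, C1qb and C1qc, and cameraPR did not call the list (adjusted p = 0.0507; 5 lower and 3 higher adjusted over the list alone). Called genes were in excess in it (Fisher adjusted p = 0.000585), and cameraPR called it lower with the trend of gene span and class removed (adjusted p = 0.00739), but not without members shared between lists (adjusted p = 0.623). Of 20 phagocytosis and lysosome genes, 3 fell and 1 rose, with the lysosomal protease Ctss at -1.45, the receptor Mertk at -0.24 and Lyz2 at 1.15 in the authors' deposited table (adjusted p = 0.522; 3 lower and 2 higher adjusted over the list alone).

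Of 9 oligodendrocyte precursor genes, 8 fell, with a median of -2.09 in the authors' deposited table (adjusted p = 6.39e-102; 8 also when adjusted over the list alone). Neu4, a sialidase (chromosome 1, 94020451 to 94028334, plus strand), fell by 4.53 with an implied SE of 0.21, the equivalent of 23.2-fold (q = 1.72e-97, the authors' deposited table). Pdgfra, the growth factor receptor that marks these cells (chromosome 5, 75152292 to 75198215, plus strand), fell by 2.09 with an implied SE of 0.12 in the authors' deposited table (q = 1.86e-69). Matn4 and Gpr17 fell too, at -3.65 and -3.28 (the authors' deposited table, q = 5.64e-73 and 3.68e-47). Enpp6 was the member not called, at 0.09 in the authors' deposited table (q = 0.91). None of the 14 myelin genes passed the threshold, while 7 had an unadjusted p under 0.05 and 2 were higher when adjusted over the list alone. Their median was 0.48, 13 of 14 lay above 0, and the list was called higher (cameraPR adjusted p = 0.000126), with Mbp at 0.66 and Cldn11 at 0.74 in the authors' deposited table (q = 0.0577 and 0.066).

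Of 24 interferon response genes, 17 fell and none rose, with a median of -1.01 in the authors' deposited table (adjusted p = 2.33e-15; 19 lower adjusted over the list alone). Ifit1, Usp18, Irf7 and Mx2 fell, at -1.41, -1.62, -1.38 and -1.14 (the authors' deposited table, q from 1.46e-05 to 5.83e-05). The cytokine list was not called as a whole (adjusted p = 0.73), with 3 of 17 genes lower: in the authors' deposited table Il1a stood at -2.17, Il18 at -0.37 and Cxcl10 at -1.77 (3 lower adjusted over the list alone).

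Of 20 cell cycle genes, 12 rose, with a median of 0.83 in the authors' deposited table (adjusted p = 4.78e-15; 16 higher adjusted over the list alone). Mcm6, a replication helicase subunit, rose by 0.45, the cyclin Ccnb2 by 0.87 and the mitotic kinases Bub1 and Aurkb by 1.65 and 1.83 in the authors' deposited table (q from 4.07e-06 to 0.00187). Of 16 cholesterol synthesis genes, 9 rose, with a median of 0.32 in the authors' deposited table (adjusted p = 1.2e-13; 11 higher adjusted over the list alone). Sqle, Fdft1 and Hmgcs1, enzymes of the pathway, rose by 0.44, 0.36 and 0.37 (the authors' deposited table, q from 1.36e-07 to 0.00018). Of 30 reactive astrocyte genes, 10 rose and 1 fell, with a median of 0.47 in the authors' deposited table (adjusted p = 7.2e-06; 12 higher and 4 lower adjusted over the list alone). Gfap, the intermediate filament of astrocytes, rose 2.82-fold with an implied SE of 0.31 on the log2 scale in the authors' deposited table (q = 0.000134), and S1pr3, Serpina3n and Aspg rose by 0.77, 1.33 and 0.93. Of 13 general astrocyte markers, Ntsr2 alone was called, at 0.28 in the authors' deposited table (list adjusted p = 0.636; 1 adjusted over the list alone).

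Mural cell genes were called higher as a list (adjusted p = 0.000166, median 0.21), with Abcc9 at 0.67 and Pdgfrb at 0.37 the 2 of 9 past the threshold in the authors' deposited table (3 adjusted over the list alone); with the log2 fold change as statistic the call was lost (adjusted p = 0.0596). Activated microglia genes were called higher (adjusted p = 0.0449, median 0.13), with the galectin Lgals3 at 1.78 and the oxidase subunit Cybb at 1.27 the 2 of 20 that rose in the authors' deposited table (3 adjusted over the list alone). That call was lost in all 6 other settings, with an adjusted p of 0.128 at a preset correlation of 0.05 and from 0.0608 to 0.236 in the others. Of 10 fibroblast and meninges genes, Lum, Dcn and Col3a1 rose by 1.58, 0.84 and 1.85, Igf2 rose too and Fmod fell, at -0.74, in the authors' deposited table (cameraPR adjusted p = 0.0507; 5 higher and 3 lower adjusted over the list alone). Called genes were in excess in this list (Fisher adjusted p = 0.000585), and with the log2 fold change as statistic cameraPR called it higher (adjusted p = 0.0143). The scavenger receptor Cd163 fell by 3.62 and Cbr2 rose by 1.06 among 11 genes of border-associated macrophages, the macrophages of the brain's linings (the authors' deposited table, list adjusted p = 0.636; 3 higher and 2 lower adjusted over the list alone). The chemokine receptor Ccr2 and the integrin Itgal rose by 1.26 and 1.58 among the 5 measured monocyte and neutrophil genes (the authors' deposited table, list adjusted p = 0.0561; 2 adjusted over the list alone). H2-Ab1 and Cd74, of the class II pathway, rose by 1.19 and 1.04 among 18 antigen presentation genes, whose median was -0.32 in the authors' deposited table (list adjusted p = 0.901; 3 higher and 1 lower adjusted over the list alone). Among 17 matrix genes, Mmp9 and Mmp14 rose by 1.29 and 0.63, and Vcan, Acan, Bcan and Tnr, which are proteoglycans and a glycoprotein of perineuronal nets or matrix, fell, at -1.13, -1.35, -0.27 and -0.62 in the authors' deposited table (cameraPR adjusted p = 0.8, Fisher adjusted p = 0.0011 for the excess of called genes in either direction; 3 higher and 5 lower adjusted over the list alone).

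No neuronal list was called at 5 dpi, but single genes passed the threshold. An unadjusted p under 0.05 was found for 8 of 14 excitatory neuron, 6 of 13 interneuron and 6 of 23 synapse genes. Over all 20375 genes there were 3883. Neurod2 rose by 0.39 among 14 excitatory neuron genes (list adjusted p = 0.149), Npy rose by 0.43 and Adarb2 and Gad1 fell, at -0.40 and -0.35, among 13 interneuron genes (adjusted p = 0.553), and Homer1 fell by 0.62 among 23 synapse genes (adjusted p = 0.208) in the authors' deposited table. Adjusted over the list alone, 4 excitatory neuron genes were higher and 1 lower, 1 interneuron gene was higher and 4 lower, and 1 synapse gene was lower. In the smaller lists, the authors' deposited table gave 0.44 for Bbc3 and 0.99 for Hmox1 among stress genes, 0.50 for Ddit4, -0.56 for Sult1a1 and -0.31 for Fkbp5 among glucocorticoid response genes, 0.39 for Dbp among clock genes, and -0.30 for the Y-linked Kdm5d, all past the threshold. The adjusted p of these lists was 0.121, 0.901, 0.73 and 0.0561, and sex-linked genes were called lower with ranks of the z (adjusted p = 0.0436) and with the trend removed (adjusted p = 0.0451). Adjusted over the list alone, 2 stress genes were higher, 1 glucocorticoid response gene was higher and 2 lower, 2 clock genes were higher and 1 lower, and 2 sex-linked genes were lower. No member passed in the lists for endothelium (adjusted p = 0.73), striatal neurons (0.253), choroid plexus and ependyma (0.529), red blood cells (0.636), lymphocytes (0.73), immediate early genes (0.738), oxidative phosphorylation (0.441) and the mitochondrial genome (0.906). Unadjusted p under 0.05 was found for 3, 1, 1, 0, 0, 2, 1 and 0 of their members, and none passed when adjusted over the list alone. The median, mean and test of a list differed in sign for interneurons, astrocytes, border-associated macrophages, endothelium, immediate early genes, matrix, antigen presentation, glucocorticoid response and the mitochondrial genome, none of them called. Against the matched random lists, some lists not called had medians near an end at 5 dpi, so a shift is not excluded. The percentile was 0.11 for antigen presentation, 0.77 for synapse and 1.3 for sex-linked genes. It was 99.96 for fibroblasts and meninges, 99.85 for border-associated macrophages and 98.99 for striatal neurons. Monocytes and neutrophils stood at 98.51 and matrix at 97.545. The other lists not called lay between 21.68 and 96.69. The random lists were not matched on transcript class and drew on classes that were lower as a whole, such as TEC. Their range for fibroblasts and meninges was -0.36 to 0.20. A high percentile of a list with large implied errors can therefore reflect transcript class as well as a shift of the list.

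**Figure D1:**
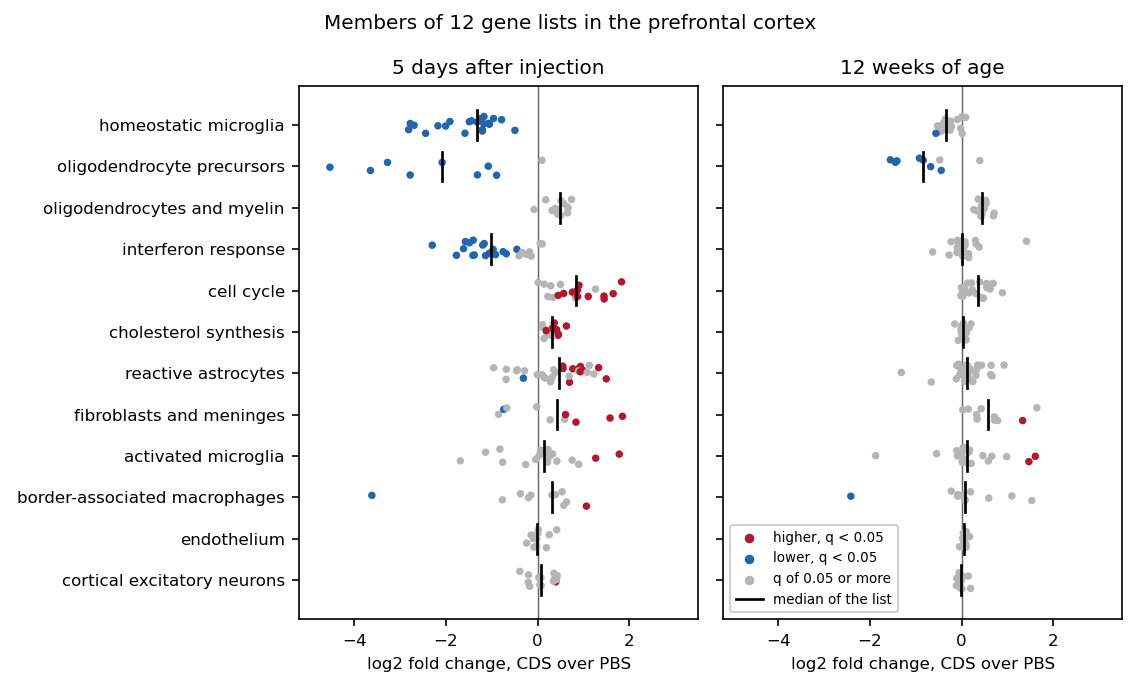
Log2 fold change of CDS over PBS (x axis) for the members of 12 gene lists (rows) at 5 days after injection (left) and at 12 weeks of age (right), from the authors' deposited table of each time. Each point is a gene, red and blue where higher or lower at q under 0.05 and grey otherwise, and black bars are list medians, which for homeostatic microglia stood at -1.32 and -0.34.

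The largest falls at 5 dpi were in Ms4a15 (-6.74, implied SE 1.80), Irx1 (-6.03, 0.99), Cd209f (-5.49, 0.96), S100a5 (-5.05, 1.70), Cd209g (-5.02, 1.04), Npffr2 (-4.72, 1.01), Gsx1 (-4.62, 1.08), Neu4, Cd209b (-4.24, 1.01) and Adamts19 (-4.15, 0.94) in the authors' deposited table. The largest rises were in Runx3 (4.59, implied SE 1.13), the neutrophil-attracting chemokine Cxcl5 (3.71, 0.29), Cyp4f18 (2.74, 0.50), Ptpn7 (2.58, 0.60), Sh2d1b1 (2.56, 0.77), Hist1h2an (2.40, 0.46), Slc14a2 (2.33, 0.77), Kcnn4 (2.32, 0.39), Hist1h3b (2.19, 0.34) and Pimreg (2.06, 0.42) in the authors' deposited table. The implied errors above 0.9 mark genes whose fold is loosely known. S100a5 and Gsx1 are among 17 genes known from the olfactory bulb that were chosen after they were seen to be lower. Of 16 other bulb markers none was called, and their median was -0.062 in the authors' deposited table. Transcripts of the annotation class TEC, loci still to be experimentally checked, had a median of -0.48 over 1441 genes in the authors' deposited table, against 0.00 for 15454 protein-coding genes. With that trend and the one with gene span removed, 1042 genes were called, 548 higher and 494 lower, and 877 of them were shared with the 1207. Of the 1207, 548 higher and 548 lower genes were protein-coding; with p adjusted anew over protein-coding genes alone, 595 were higher and 599 lower.

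The comparison at 12 weeks asked what remained 6 weeks after injection. The lists of oligodendrocyte precursors and homeostatic microglia were still lower in CDS, with 7 genes of the first and 1 of the second past the threshold. Col15a1, Col13a1 and Lum were higher, as were Spp1 and Cybb. In the authors' deposited table, 39 genes had a q under 0.05, 19 of them higher and 20 lower in CDS; 16 differed by at least 2-fold, 6 higher and 10 lower, and 20103 genes shared the highest q.

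Of the 9 precursor genes, 7 fell at 12 weeks, with a median of -0.84 in the authors' deposited table (cameraPR on ranks, adjusted p = 0.000688; at least 7 adjusted over the list alone). The same cameraPR test on ranks gave an adjusted p of 0.000227 at 5 dpi, where the signed z was used above. Neu4 (-1.56, implied SE 0.17), Matn4 (-1.44, 0.16), C1ql1 (-1.41, 0.15) and Pdgfra (-0.84, 0.11) fell in the authors' deposited table (q from 6.67e-17 to 5.61e-10). Gpr17, Cspg4 and Lhfpl3 fell, at -0.92, -0.68 and -0.45, as did the lineage transcription factor Olig2, at -0.50, in the authors' deposited table. Myelin genes lay above 0 in 14 of 14 cases with a median of 0.44 (adjusted p = 5.72e-07), although none passed the threshold, with Ermn at 0.69 and Mobp at 0.71 in the authors' deposited table (q = 0.808 and 0.913). Markers of striatal neurons lay above 0 too, in 9 of 9 cases with a median of 0.33 (adjusted p = 0.00018), as did 9 of 10 choroid plexus and ependyma genes with a median of 0.36 (adjusted p = 0.000688).

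The homeostatic microglia list was lower as a whole at 12 weeks (adjusted p = 1.2e-05), with a median of -0.34 and 18 of 21 genes below 0 in the authors' deposited table. With cameraPR on ranks, as used here, its adjusted p at 5 dpi was 8.53e-11. Slc2a5 fell by 0.56 with an implied SE of 0.13 (the authors' deposited table, q = 0.00592), and at least 5 genes were lower when adjusted over the list alone. Selplg stood at -0.53, Cx3cr1 at -0.47, Csf1r at -0.46, P2ry13 at -0.44, P2ry12 at -0.40, Tmem119 and Itgam at -0.34 and Aif1 at -0.33 in the authors' deposited table, none of them past the threshold. Gfap stood at 0.63, not past the threshold (the authors' deposited table). Of 20 activated microglia genes, the secreted phosphoprotein Spp1 rose by 1.61 (implied SE 0.31) and Cybb by 1.47 (0.32) in the authors' deposited table (q = 0.000347 and 0.00341; list adjusted p = 0.0194, and adjusted p = 0.0791 at a preset correlation of 0.05; at least 3 adjusted over the list alone). Cd163, Cd209b and Cd209f fell, at -2.42, -2.94 and -2.59 in the authors' deposited table, while the other 10 border-associated macrophage genes of the list did not pass (list adjusted p = 0.343; at least 2 higher and 1 lower adjusted over the list alone). H2-Ab1 rose by 0.93 among antigen presentation genes (the authors' deposited table, q = 0.0343; list adjusted p = 0.00811, and adjusted p = 0.056 at a preset correlation of 0.05; at least 3 adjusted over the list alone), and Vcan fell by 0.60 among matrix genes (list adjusted p = 0.641; at least 1 adjusted over the list alone).

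Col15a1, a collagen of basement membrane zones, rose by 1.61 with an implied SE of 0.14 in the authors' deposited table (q = 1.65e-24). Lum rose by 1.33, Col13a1 by 1.31, Postn by 1.18, Edn3 by 0.96, Col4a6 by 0.83 and Enpp1 by 0.78 in the authors' deposited table. All 10 fibroblast and meninges genes lay above 0 with a median of 0.57 (adjusted p = 5.7e-05), Lum being the one past the threshold in the authors' deposited table, and at least 4 were higher when adjusted over the list alone. Further falls among the largest were Lad1 (-2.10), Snx22 (-1.12), Gucy2f (-1.11) and Inava (-1.05) in the authors' deposited table.

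Among other lists with no gene past the threshold at 12 weeks, those called were higher for cell cycle (median 0.35, adjusted p = 7.71e-06), reactive astrocytes (0.12, adjusted p = 0.0042), endothelium (0.06, adjusted p = 0.0285), astrocytes (0.08, adjusted p = 0.0285), stress (0.06, adjusted p = 0.0285), mural cells (0.12, adjusted p = 0.036) and phagocytosis and lysosome (0.06, adjusted p = 0.0367). Of these, all but cell cycle lost the call at a preset correlation of 0.05: reactive astrocytes (adjusted p = 0.0571), astrocytes, endothelium and mural cells (adjusted p = 0.0791 for each), stress (adjusted p = 0.0794) and phagocytosis and lysosome (adjusted p = 0.126). With the log2 fold change as statistic the last 5 of these calls were lost as well (adjusted p from 0.187 to 0.487). Adjusted over the list alone, at least 1 phagocytosis and lysosome gene was higher. Red blood cell genes were lower (-0.98, adjusted p = 0.000728), while the same statistic had called them higher at 5 dpi (adjusted p = 0.00792). With the signed z they were not called at 5 dpi (cameraPR adjusted p = 0.636). None of the 5 had an unadjusted p under 0.05 at 5 dpi, nor at 12 weeks with the 5 dpi error. Globin genes share reads and are not independent, so these opposite calls do not establish a reversal. The mitochondrial genome was lower (-0.14, adjusted p = 0.0285), a call lost at 0.05 (adjusted p = 0.0679) and with the log2 fold change (adjusted p = 0.429). In all, 17 of 33 lists were called at the preset correlation of 0.01 and 8 at 0.05. Called genes were in excess in the lists of precursors (Fisher adjusted p = 6.31e-17) and activated microglia (Fisher adjusted p = 0.011). Not called were interferon response (median 0.01, adjusted p = 0.584), cholesterol synthesis (0.02, adjusted p = 0.234), complement (0.01, adjusted p = 0.481), synapse (-0.04, adjusted p = 0.0809), cytokines (0.05, adjusted p = 0.232), monocytes and neutrophils (-0.44, adjusted p = 0.139) and immediate early genes (0.08, adjusted p = 0.269). With the log2 fold change as statistic, cytokines were called higher (adjusted p = 0.00168; adjusted p = 0.0258 when divided by the 5 dpi error) and monocytes and neutrophils lower (adjusted p = 0.00391). Also not called were lymphocytes (adjusted p = 0.288), oxidative phosphorylation and glucocorticoid response (adjusted p = 0.343 for both), clock (0.626), sex-linked genes (0.756), interneurons (0.829) and excitatory neurons (0.829), the last with a median of -0.01 and a mean of 0.00. Among matched random lists at 12 weeks, the called lists of stress and the mitochondrial genome had medians at percentiles 96.86 and 2.8. Synapse, not called, stood at 2.57.

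The overlap of both comparisons asked whether the genes past the threshold at 12 weeks were those of 5 dpi. Of the 20 genes lower at 12 weeks, all 20 were lower at 5 dpi, against 0.635 for independent lists (two-sided Fisher exact p = 8.15e-31). Of the 19 higher, 16 were higher at 5 dpi, against 0.522 (Fisher exact p = 7.71e-23). Spp1, Fbln2 and Acot11 were called at 12 weeks but not at 5 dpi, where the authors' deposited table gave 0.03, 0.42 and 0.09. In 30 of the 39 genes the change was smaller in size at 12 weeks. Across all genes, which are not independent replicates, the log2 fold changes of the authors' deposited tables correlated with Pearson's r of 0.297 and Spearman's rho of 0.242. No control samples are shared between the tables.

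**Figure D2:**
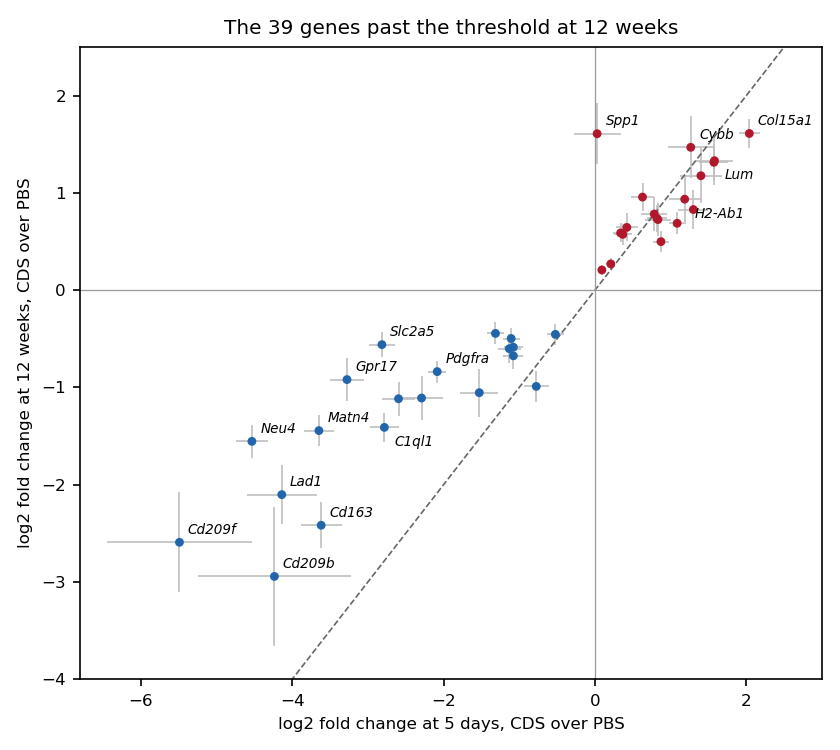
Log2 fold change of CDS over PBS at 5 days (x axis) and at 12 weeks (y axis) for the 39 genes past the threshold at 12 weeks, from the authors' deposited tables, with bars of 1 implied SE. Red genes were higher and blue genes lower at 12 weeks, the dashed line marks equal change, and 30 of the 39 genes lie nearer to 0 at 12 weeks.

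The difference between the times tested whether the CDS effect itself changed. Microglial and precursor genes were less reduced at 12 weeks than at 5 dpi. Of the 272 genes with errors recovered at both times, 47 differed, 38 with a higher and 9 with a lower log2 fold change at 12 weeks. These 272 genes were selected for small p at 12 weeks, which can inflate the count of 47. Of the 47, 33 were called at 5 dpi and 14 were not. All 33 were closer to 0 at 12 weeks, an outcome that selection for a large effect at 5 dpi favors. From the values of the authors' deposited tables, Neu4 differed by 2.98 (SE 0.27, adjusted p = 9.3e-26) and Tmem255b by 3.43 (SE 0.43, adjusted p = 8.5e-14). Over all 20375 genes, with the error of 5 dpi for those lacking one at 12 weeks, 88 differed, 71 higher and 17 lower at 12 weeks, of which 85 had been called at 5 dpi. There P2ry12 differed by 2.30 (adjusted p = 1.54e-14), Slc2a5 by 2.25 (adjusted p = 3.48e-22), Pdgfra by 1.25 (adjusted p = 3.73e-11) and Ifit1 by 1.40 (adjusted p = 0.0473), from the values of the authors' deposited tables. For Spp1, called at 12 weeks alone, the difference of 1.58 did not pass (adjusted p = 0.0685, the authors' deposited tables).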

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

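Of the tests in this part, those for loss of neuroblasts, white matter, the olfactory bulb in the precursor pattern, host genes as the whole cause, noise and library size were chosen after the result was seen. The test of lists between times was also chosen after the data were seen. Intervals by resampling genes treat genes of the same samples as independent and hold no spread between samples.

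The CDS effect differed between 5 dpi and 12 weeks for 47 of the 272 genes with errors recovered at both times. Differences are log2 fold changes at 12 weeks minus those at 5 dpi, from the authors' deposited tables. Irx1 differed by 4.41, Tmem255b by 3.43, Wnt9b by 3.11, Neu4 by 2.98 and Cd209f by 2.90. In the other direction Lif differed by -1.72, Hbq1a by -1.31, Mmp2 by -1.07, Tgfbi by -0.98 and Pde2a by -0.67. Lif, Hbq1a, Mmp2, Pde2a and Wnt9b were called at neither time, and the 272 genes were those with the smallest p at 12 weeks. Over all genes Irx1, Tmem255b and Neu4 passed, while Lif (adjusted p = 0.127), Hbq1a (0.147), Mmp2 (0.144), Tgfbi (0.192), Pde2a (0.0517), Wnt9b (0.105) and Cd209f (0.334) did not.

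Lists whose effect differed between the times (cameraPR over all genes, preset correlation 0.01) were homeostatic microglia, with a median difference of 1.09 (adjusted p = 3.78e-70), oligodendrocyte precursors, with 1.25 (adjusted p = 1.44e-43), and interferon response, with 0.94 (adjusted p = 1.03e-17). The median difference was -0.29 for cholesterol synthesis, -0.43 for cell cycle, -0.92 for monocytes and neutrophils, -0.28 for reactive astrocytes, 0.083 for complement, -0.20 for mural cells and -1.27 for red blood cells (adjusted p from 8.57e-12 to 0.0448). At a preset correlation of 0.05 the calls of complement (adjusted p = 0.0587), mural cells (0.0784), red blood cells (0.0791) and reactive astrocytes (0.0823) were lost. No red blood cell or mural cell gene differed on its own.

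Genes known from the olfactory bulb, such as Tbx21, Eomes, Doc2g and Th, were lower in CDS at 5 dpi (-3.97, -2.97, -2.70 and -1.60, the authors' deposited table); a set of 17 chosen for this pattern had a median of -2.17, with 14 past the threshold. Loss of migrating neuroblasts alone stays open: 7 markers of mitral and tufted cells, which are not made in the adult, had a median of -1.73, but 6 of them were among the 17 genes chosen for being lower. Less bulb tissue in the CDS dissections may account for the pattern and stays open too. Its test used 16 markers held out. Their median lay at percentile 31.1 of matched random lists, past the bound of 25 set beforehand against it. But those markers had a median implied SE of 0.17 against 0.64 for the 17 genes. A higher level in cortex, inferred from that and not measured, could hide a small share of bulb RNA. In that case the bound was poorly chosen. That reason was given after the value was seen.

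Oligodendrocyte precursor genes were lower in CDS at both times, while myelin genes were not. Less white matter in the CDS dissections is argued against by the myelin list, whose median was 0.48 at 5 dpi, and a trend with gene length and transcript class by the precursor median of -2.07 once it was removed. Less bulb tissue as the whole cause would need bulb genes to fall at least as far as precursor genes, which the whole brain expresses. At 5 dpi the sets of bulb genes differed on this. The 17 genes, at -2.17 against -2.09, met that need, but they were chosen for being lower. Against it are the 16 held-out markers, with a median of -0.062 (95% interval by resampling genes -0.37 to 0.037). The implied SE of these 16 was like that of the precursor genes (0.17 and 0.20), taken in place of a level, as no mean levels are given. Their level in cortex, raised above as a limit, was not measured. At 12 weeks the median of the 17 bulb genes lay 0.54 above that of the precursor genes (95% interval 0.016 to 1.38). That margin is too narrow to decide, since resampling genes leaves out the spread between samples. A part played by less bulb tissue stays open. The 17 genes had a median of -2.17 at 5 dpi. At 12 weeks both outcomes named for its test were met: 7 precursor genes passed and none of the 17 did. Yet the median of the 17, -0.29, lay at percentile 2.65 of matched random lists. A lower number of precursor cells after CDS remains a hypothesis beside less bulb tissue, as the tables hold no cell counts.

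TEC and sense-intronic transcripts were lower in CDS at 5 dpi as classes, with medians of -0.48 and -0.52. Few passed the threshold singly: of 1441 TEC genes 45 fell and 1 rose, and of 187 sense-intronic genes 3 fell. Over all 20375 genes, 1207 passed. Among other noncoding classes, miRNA and snoRNA had medians of -0.41 and -0.26, and antisense, lincRNA and processed transcripts of -0.02, -0.09 and -0.08. Noise of low genes is argued against by the 90.1% of TEC genes below 0, and library size normalization by the difference of -0.49 between the medians of TEC and protein-coding genes. Both values restate the pattern itself and are not separate tests of it. A lower share of unspliced RNA in the CDS libraries is a candidate explanation for a part: 1054 TEC genes inside a protein-coding gene on its strand had a median of -0.58, against -0.32 for 258 outside such genes (difference -0.26, 95% interval by resampling genes -0.34 to -0.20, whose upper end touches the bound of -0.2 set beforehand). Unspliced RNA of host genes as the whole cause is argued against by that median of -0.32 outside (95% interval -0.37 to -0.24), with 78.7% below 0, and processed pseudogenes stood at -0.30. Whether such a share would come from the tissue or from RNA handling was not tested.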

How the results depend on the processing

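Recounts over protein-coding genes, with the trend removed, and with the 5 dpi error at 12 weeks were chosen after the data were seen. The list counts at 12 weeks rest on ranks of the log2 fold change, which replaced the planned signed z. The rest were planned. At 5 dpi the 1207 genes became 600 at q under 0.01, 603 at a fold of at least 1.5 and 219 with Bonferroni adjustment, fewer by construction of each rule; they were 1754 at q under 0.1, 1194 with p adjusted anew over protein-coding genes alone (595 higher, 599 lower) and 1042 with the trend with span and class removed (548 higher, 494 lower), against 560 higher and 647 lower. At 12 weeks the 39 genes became 20 with Bonferroni adjustment, 28 at q under 0.01, 31 at a fold of at least 1.5 and 45 at q under 0.1; with the 5 dpi error for all genes they were 38 (23 higher, 15 lower), 34 of them shared. List calls at 5 dpi stayed between 8 and 10 of 33 against 9, and 7 of the 9 were called in each of the 6 other settings; activated microglia and mural cells were the exceptions. At 12 weeks 17 lists became 8 at a preset correlation of 0.05, a stricter rule by construction, and 13 to 17 otherwise, with 8 called in each of the 4 other settings. The genes that differed between times were 47, 69 at an adjusted p under 0.1, 39 among genes past the threshold at either time, and 88 over all genes, with the 5 dpi error where none was recovered at 12 weeks; the overlap of 36 became 39 at q under 0.1. No called list or named gene turned direction in these settings. Of the named genes called at 5 dpi, 82 stayed past the threshold with the trend removed and 7 did not.

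No paired analysis was possible because the tables hold no per-sample values. For the same reason replicates left out in turn, other count models and scalings, other pseudocounts and an estimated correlation were not run, and other splits of the samples could not be counted. Filters on mean level were not run, since no mean level is given, nor the overlap at an unadjusted p, which the tied q hides at 12 weeks. Recomputing the adjusted p would return the deposited q by construction. Depth is unknown, and the spread it leaves shows in the implied SE, with quartiles of 0.09 and 0.30 at 5 dpi.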

Other observations

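The gene families below were not themselves fixed lists, were chosen after their values were seen and were not tested for enrichment. Some of their members are in fixed lists. Col1a1, Col1a2 and Col3a1 are in that of fibroblasts and meninges, and Oas1a and Oasl2 in that of interferon response. The counts of collagen and Oas genes thus partly restate those lists. Of 55 replication-dependent histone genes, 15 rose and none fell in the authors' deposited table, with a median of 0.32; none was called at 12 weeks, where the median was 0.14. These genes are known to be expressed in dividing cells, and their transcripts, which mostly lack a poly(A) tail, are kept by libraries made from ribosome-depleted RNA. Of 45 collagen genes, 18 rose and 3 fell at 5 dpi, and 3 rose at 12 weeks. Of 11 laminin genes, 6 rose and 1 fell at 5 dpi, and 2 rose at 12 weeks, Lama1 standing at 1.09 and 0.69 in the authors' deposited tables. Both nidogens, which link collagens and laminins in basement membranes, rose at 5 dpi, Nid1 by 1.07 and Nid2 by 0.72 (the authors' deposited table).

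Of 8 genes of the Oas family, which sense double-stranded RNA, 5 fell at 5 dpi and none was called at 12 weeks, with medians of -1.04 and 0.03 in the authors' deposited tables. Cd209b, Cd209f and Cd209g fell at 5 dpi together with Cd163, while Mrc1, Lyve1 and Pf4, markers of the same border macrophages, stood at -0.20, -0.38 and 0.57 and were not called (the authors' deposited table). None of 76 cytosolic ribosomal protein genes was called at either time, and their medians were -0.00 and 0.03.

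Protein-coding fold changes followed genomic span weakly. In 5 bins of 15454 genes by span, from the shortest to the longest, the median went from 0.07 to -0.06 at 5 dpi and from 0.02 to -0.01 at 12 weeks, and Spearman's rho across genes was -0.222 and -0.0852. Of the 1207 genes called at 5 dpi, 887 (73.5%) had the same sign at 12 weeks, against 57.2% of all genes, and the 12-week median was -0.08 for those lower and 0.07 for those higher at 5 dpi.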
